A study of Mus musculus with 4 samples.

How the data were processed

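Single ILC2 from mouse pancreas were index-sorted into 4 plates of 384 wells and made into libraries with a CEL-seq2-based SORT-seq protocol, per the labels' protocols. The authors deposited a table of raw read counts per row and well, and a sort record with the plate, well, sort batch, colour and red fluorescence intensity of each well. Per the submitters' processing notes, STAR, STARsolo and edgeR were used with the mm10 build, and no version or role was given. The values are read counts and not counts of molecular identifiers, as a maximum of 147279 in a single row and well shows. Per the file headers, the deposited fluorescence intensity is in arbitrary units and can be negative, and it was used as given. Each plate is 1 GEO sample and was treated as 1 replicate. The labels do not say which plates share an animal, so the spread between plates may be technical.

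The row names were checked against each plate before any gene was used. Values were present in 11430, 11059, 11291 and 11430 rows of plates 1 to 4, and 0 of these rows lacked reads on any plate, as if each plate's own detected genes had been listed. The position of the row block with most reads, the spike-in rows, the mitochondrial rows and the correlation of detection between plates were compared. The names were used for plate 1 only, and no row of plates 2 to 4 was named. For these plates only values per well were used, over all rows, since spike-in rows could not be told from genes there.

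The test fixed before the data were examined was edgeR's quasi-likelihood test on counts summed per plate and colour, with plate as a block and at least 10 cells per sum. It could not be fitted as written, because rows do not name the same gene on different plates and each sum of photoconverted cells that passed the filter held 5 to 8 cells. Plate 1 alone gives 1 sum per colour and leaves no residual degrees of freedom. The planned gene set tests rest on the same fit. In their place, descriptive values were computed for plate 1. These measures, the naming rule below and the alternatives that go with them were chosen after the data were seen.

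Cells needed at least 500 genes at 1 read or more and under 25% mitochondrial reads, a filter fixed before the data were examined. On plates 2 to 4 it used all rows and no mitochondrial limit. It kept 8 photoconverted and 98 non-photoconverted cells of plate 1, 5 and 105 of plate 2, 5 and 98 of plate 3, and 8 and 105 of plate 4. For the share of cells with a gene, it counted as detected in a cell at 16 reads or more, because values of few reads were frequent in empty wells: their median number of genes was 92 at 1 read and 3 at 16 reads, against 1005 and 445 in non-photoconverted wells. Each photoconverted cell was matched to the 5 non-photoconverted cells nearest in log genes at 1 read or more, which gave 29 distinct cells with the weight of 22.9 equal ones. As further measures, each cell was drawn down to 1000 reads by the exact expected share (0 cells of either colour fell below), and mean CPM was compared after adding 10. Both of these were set against all non-photoconverted cells unless they are called depth-matched. Drawn-down cells still differed in the number of genes, with a mean of 453 in photoconverted and 366 in non-photoconverted cells. No doublet caller was run on single sorted cells.

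The 31 gene lists and cell type markers were fixed before the data were examined, and 23 had at least 5 members with reads on plate 1. Each list's median difference in share was placed among 10000 random lists of the same size drawn from the same 20 expression bins. The percentile describes these libraries, takes no account of correlation between genes and is not a test. Named genes were, among genes detected in at least 4 photoconverted cells or 25% of non-photoconverted cells, the 12 with the largest difference in each direction from depth-matched cells whose drawn-down difference had the same sign, with ties at the limit broken by name. Ribosomal protein genes, numbered gene models and pseudogenes were skipped. Of each fixed list, the 3 members with the highest mean CPM could be named, as planned; further members (among them Pgam1, Aldoa, Pgk1, Gapdh, Slc2a3, Il5, Csf2, Il13, Rora, Mki67 and Calcrl) were named after their values were seen. Coordinates are from GENCODE M21, on mm10. In 20 simulated data sets, in which 8 non-photoconverted cells stood in for photoconverted cells and 200 genes were raised by detecting them in 50% of the cells that lacked them, 94.1% of the raised genes came out higher, against 45.1% of unchanged genes (median 2331 genes per set), and the planted list of 20 genes lay above the central 95% of random lists in 20 of 20. An unchanged list of 20 genes lay outside it in 2 of 20. The planted rise was larger than the list differences reported below, so smaller differences were not covered.

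Plate 1 cells were clustered on log-normalised counts (2000 variable genes, 20 components, 15 neighbours, Leiden resolution 0.5). Values per well were compared within plate by an exact two-sided test over all 16 swaps of the colours within plates, with Benjamini-Hochberg adjustment over 3 measures. This test was planned for fluorescence and cluster shares, and its use on detected rows, reads and filter passes per well was chosen after the data were seen. Clusters were on 1 plate and were not tested. Shares have exact (Clopper-Pearson) 95% intervals, and a count of 0 was taken to allow 3 counts. Alternatives were the cell filter, the detection limit, the measure, the matching, the clustering settings and leaving out each plate, photoconverted cell or depth-matched cell. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9 were used.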

Results

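Group 2 innate lymphoid cells (ILC2), tissue lymphocytes known for making interleukin-5, interleukin-13 and amphiregulin, were sorted from mouse pancreas as single cells into 4 plates of 384 wells and sequenced with SORT-seq, a CEL-seq2-based method that reads the 3' ends of polyadenylated RNA. The cells carried KIKR, a fluorescent protein that turns from green to red where it is exposed to violet light. A red (photoconverted) cell carries a mark of earlier exposure and a green (non-photoconverted) cell does not. The sort record gave 1129 non-photoconverted cells, 41 photoconverted cells and 366 wells left empty. Photoconverted cells made up 7.36% of the 163 sorted cells on plate 1 (12 cells, exact 95% binomial interval 3.86 to 12.5%), 2.45% of 368 on plate 2 (9 cells, 1.12 to 4.59%), 2.15% of 372 on plate 3 (8 cells, 0.933 to 4.19%) and 4.49% of 267 on plate 4 (12 cells, 2.34 to 7.72%). The plates held 52614294, 40228604, 32723492 and 41140830 reads. The design implies a comparison of photoconverted with non-photoconverted ILC2, and the study's title asks about fasting, but neither the labels nor the sort record gives a feeding state or an animal for any cell, so no comparison of feeding states was made.

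Gene names could be used on plate 1 only. In the table of 11430 rows, the row names fitted plate 1, where the 78 rows named as spike-in RNAs (ERCC synthetic transcripts, usually added in equal amount to each well) held 43.2% of all reads and mitochondrial rows 5.63%. The rows named as spike-ins held 0.113%, 44.1% and 21.7% on plates 2, 3 and 4. Their share alone does not tell plate 1 from plate 3. On plates 2, 3 and 4 the rows named as mitochondrial held 0.0531%, 0.0110% and 0.0204%. A block of 78 rows with 61.8%, 63.3% and 63.5% of the reads of these plates started 119 rows before, 12 rows before and 61 rows after the rows named as spike-ins. The number of wells with reads per row correlated between plate 1 and the other plates with a Spearman rho, across rows, of 0.0173 to 0.0764, against 0.882 between random sets of 81 wells each of plate 1. Values of named genes are therefore given for plate 1 alone, which makes them values of 1 sample without replicate, and no p-value was computed for any gene.

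**Figure D1:**
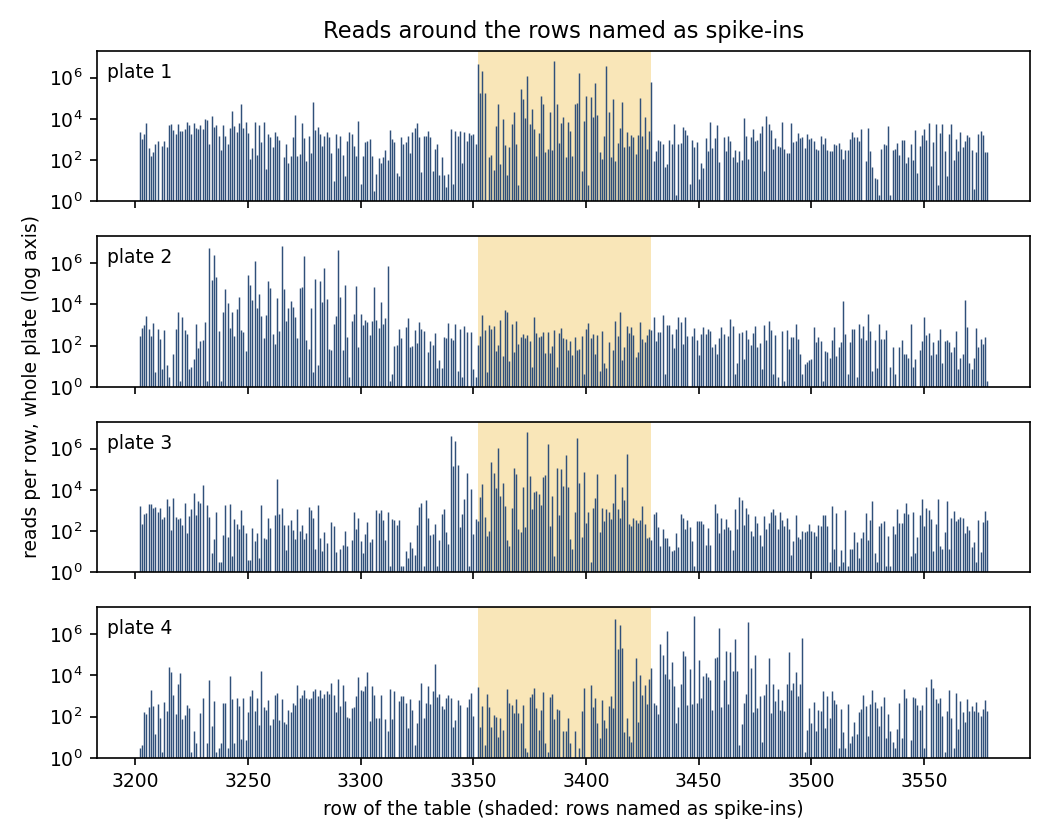
Reads per table row summed over all wells of each plate (log axis), for the rows around those named as spike-ins (shaded). The block of high rows lies on the shaded rows on plate 1 and starts at row 3233 on plate 2, 3340 on plate 3 and 3413 on plate 4, against 3352 on plate 1.

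On plate 1, 8 photoconverted and 98 non-photoconverted cells passed the filter, and transcripts typical of ILC2 were detected in both, to unequal extents. Gata3, the master transcription factor of the lineage (chromosome 2, 9857078 to 9890034, mm10), had 16 or more reads in 8 of 8 photoconverted cells (exact 95% interval 63.1 to 100%) and in 83.7% of non-photoconverted cells (74.8 to 90.4%), against 3.17% of the 221 empty wells. Il1rl1, the receptor for interleukin-33 (chromosome 1, 40429570 to 40465415), was detected in 8 of 8 and in 69.4% (59.3 to 78.3%), and Klrg1, a surface receptor of mature ILC2, in 8 of 8 and in 57.1% (46.7 to 67.1%). Rora, another transcription factor of the lineage, was detected in 2 of 8 and in 6.12% (2.28 to 12.9%). Median spike-in reads were 59283.5 in photoconverted and 67405 in non-photoconverted cells, and so do not show deeper sequencing of the photoconverted ones. Photoconverted cells still gave more reads of genes, with a median of 540662 against 187690. Their median number of genes was 2748.5 at 1 read or more and 1834.5 at 16 or more, against 1637 and 863.5. Shares were therefore also set against depth-matched non-photoconverted cells (the 5 nearest in genes at 1 read or more to each photoconverted cell, 29 distinct cells, median 2718.5 genes), of which 95% had Gata3, and 87.5% each had Il1rl1 and Klrg1. Intervals cover counting error of cells only, and reads amplified by PCR are not independent molecules.

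Transcripts of glycolysis and of several effector cytokines were detected in a larger share of the photoconverted than of the depth-matched cells. The place of the cell cycle list below random lists rested on 2 non-photoconverted cells. Of 19 measured glycolysis genes, 14 were higher, 3 lower and 2 equal. Pgam1, a phosphoglycerate mutase (chromosome 19, 41911923 to 41918660), was detected in 6 of 8 photoconverted cells (34.9 to 96.8%), in 12.2% of all non-photoconverted cells (6.49 to 20.4%) and in 32.5% of the depth-matched ones. Pkm, pyruvate kinase, was detected in 7 of 8 cells, 54.1% and 72.5%, with a mean of 1196 and 486 reads per 1000000 (CPM) in photoconverted and in all non-photoconverted cells, as for each mean CPM below. Aldoa, Pgk1 and Gapdh, further enzymes of the pathway, were each detected in 7 of 8 photoconverted cells and in 65%, 62.5% and 70% of depth-matched cells, whereas Slc2a3, a glucose transporter, was detected in 0 of 8 and in 15%. Ldha, lactate dehydrogenase, stood at 87.5% in both. The median difference over the list, 12.5 percentage points, lay at the 99.2th percentile of 10000 random lists of equal size and expression. It lay at the 94.1th percentile without photoconverted cell 6, and at the 83.8th against 8 non-photoconverted cells drawn at random.

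Among 18 measured effector cytokines and secreted products, 10 were detected in a larger share of photoconverted cells, 5 in a smaller share and 3 in an equal one, with a median difference of 11.3 percentage points at the 99.3th percentile. Il5, which drives eosinophils (chromosome 11, 53720794 to 53725106), was detected in 7 of 8 photoconverted cells (47.3 to 99.7%), in 23.5% of all non-photoconverted cells (15.5 to 33.1%) and in 47.5% of depth-matched cells. Cxcl2, a chemokine for neutrophils, was detected in 6 of 8, 25.5% and 37.5%, with a mean of 6017 CPM in photoconverted and 1363 in all non-photoconverted cells. Csf2 (GM-CSF) was detected in 6 of 8, 36.7% and 45%, Calca (the precursor of calcitonin gene-related peptide) in 6 of 8, 37.8% and 42.5%, and Areg (amphiregulin) in 7 of 8, 66.3% and 72.5%. Il13 went the other way: it was detected in 0 of 8 photoconverted cells, which allows a share of up to 37.5%, in 8.16% of all non-photoconverted cells (3.59 to 15.5%) and in 20% of depth-matched cells. By mean CPM against all non-photoconverted cells the list lay at the 92.7th percentile, inside the central 95%, and by mean CPM against depth-matched cells at 98.66. By depth-matched share it lay at the 86.4th without photoconverted cell 1. By share against all non-photoconverted cells, without depth matching, it lay at the 33.1th.

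Of the 98 non-photoconverted cells, 2, called dividing here, held 22 and 15 of the 25 measured cell cycle genes, against at most 5 in a photoconverted cell. Some genes of the list were detected well beyond these cells: Tubb5 in 45, Hmgb2 in 26, Pcna in 25 and Mcm3 in 14 of the non-photoconverted cells. Mki67, a marker of dividing cells, was detected in 0 of 8 photoconverted cells and in 3.06% of non-photoconverted cells (0.636 to 8.69%). Each of the 2 cells was depth-matched to 3 photoconverted cells, so that together they made up 15% of the matched cells. With them, 22 genes were lower in photoconverted cells, with a median difference of -10 percentage points, below that of each of 10000 random lists (percentile 0). Without them, 10 were lower, 3 higher and 9 equal among those still measured, with a median difference of 0 at the 52.3th percentile, so the list's place outside the random lists rests on these 2 cells, which were picked for holding its genes.

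**Figure D2:**
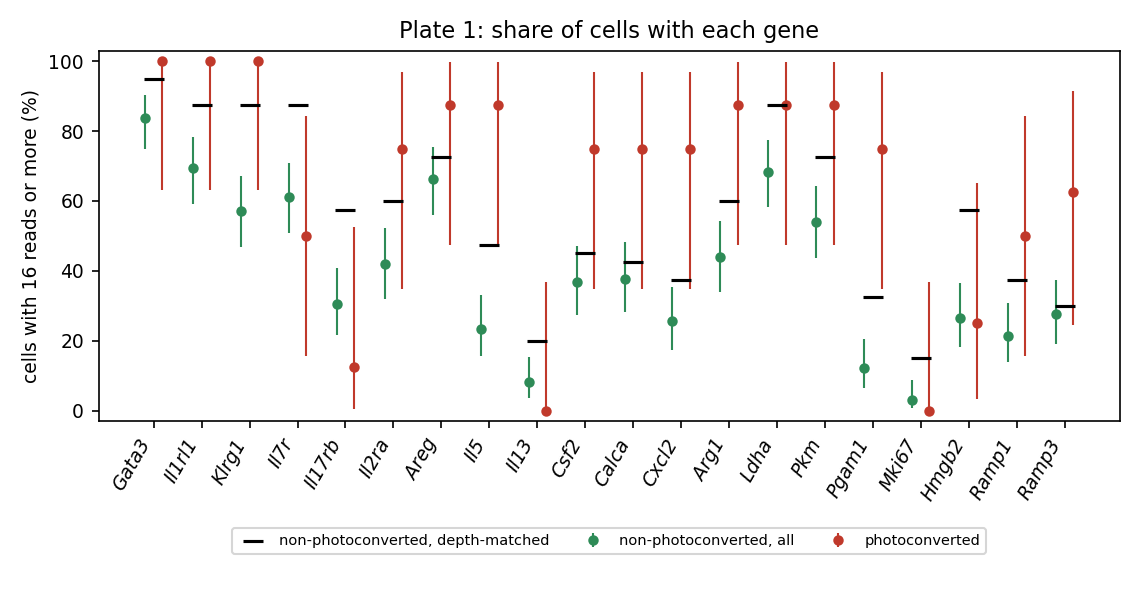
Share of plate 1 cells with 16 reads or more of each gene, in 8 photoconverted cells (red) and 98 non-photoconverted cells (green), with exact 95% binomial intervals, and in depth-matched non-photoconverted cells (black dashes, a weighted share without interval). Il5 stands at 87.5% against 47.5% in depth-matched cells, and Il17rb at 12.5% against 57.5%.

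Receptors for nerve signals were detected in few cells, and 7 of the 12 measured were higher in photoconverted cells, 2 lower and 3 equal (median difference 5 percentage points, 98.4th percentile). Calcrl and its partners Ramp1 and Ramp3, which together form receptors for calcitonin gene-related peptide and adrenomedullin, were detected in 4, 4 and 5 of 8 photoconverted cells and in 25%, 37.5% and 30% of depth-matched cells. The list lay at the 53.8th percentile without the 2 photoconverted cells near the sort boundary at the 54.9th without photoconverted cell 7, at the 51.4th with detection at 64 reads, and, below the middle, at the 35.6th against 8 non-photoconverted cells drawn at random. The ILC2-like marker list, which shares Il5, Il13 and Areg with the cytokine list, had a median difference of 11.3 percentage points (97.51th percentile, at the edge of the central 95%; 100th drawn down and 99.8th by mean CPM) with 10 of 14 markers higher and 4 lower. Its lower members included Il17rb, the receptor for interleukin-25 (1 of 8 cells against 57.5%), and Il7r, the interleukin-7 receptor (4 of 8 against 87.5%). Without photoconverted cell 8 that list lay at the 40.3th percentile by share. Drawn down and depth-matched it stayed at 99.75 or more without any 1 photoconverted cell. Most of its measured markers, among them Gata3, Il1rl1, Klrg1, Il7r and Il17rb, are also in the ILC2 identity list. That broader list lay inside the central 95%, at 74.265 by share, 29.44 drawn down and depth-matched, and 41.46 by depth-matched mean CPM. The ILC2-like values therefore do not show a general rise of ILC2 identity genes.

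Other fixed lists lay inside the central 95% of random lists by depth-matched share, and 1 of them is not reported here or plotted. Interferon response lay at the 96.8th percentile (99.1th after drawing down, and 38.5th without photoconverted cell 1), autophagy and starvation response at the 90.1th and fatty acid uptake and oxidation at the 85.9th. Tissue egress and circulation (78.9th), ILC2 identity (74.3th), intestinal ILC2 (56.1th), immediate early genes (54.3th), T cell-like markers (52.8th) and mitochondrially encoded genes (51.7th) lay in the middle. Inhibitory and costimulatory receptors (40.5th), tissue residency (36.4th), antigen presentation (34.2th), chemokine receptors and integrins (34.0th), progenitor-like ILC (22.2th), NK or ILC1-like markers (21.6th), glucocorticoid response (13.1th) and ILC3-like markers (4.71th) lay lower. In all, 5 of 23 lists lay outside, where 1.15 would by chance if lists were independent. In 20 simulated draws, in which 8 non-photoconverted cells of like depth stood in for the photoconverted ones, 0 to 4 lists lay outside (mean 1.65). The count of 5 depends on the processing. It was 2 without the 2 dividing non-photoconverted cells, 2 with the same number of cells from each colour, and as high as 7 under other alternatives. An excess over such draws is therefore not established.

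**Figure D3:**
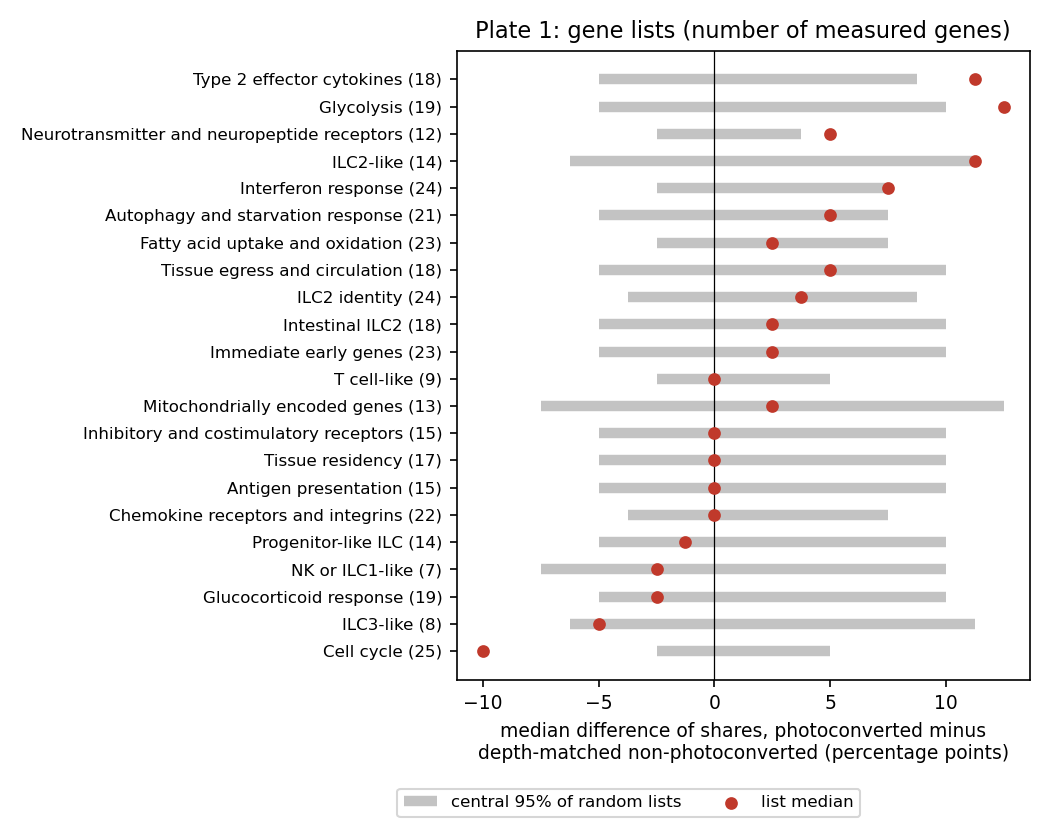
Median difference in the share of plate 1 cells with each gene (percentage points, photoconverted minus depth-matched non-photoconverted) for gene lists (points), with the central 95% of 10000 random lists of equal size and expression (grey bars). Glycolysis (12.5) and cell cycle (-10) lie outside their bars, the latter only with 2 dividing non-photoconverted cells included.

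Among single genes detected in 4 or more photoconverted or 25% or more of non-photoconverted cells (1279 genes), the largest differences towards photoconverted cells were at Ubl3 and Chtop (each 62.5 percentage points above depth-matched cells), and Gak, Eya2, Elk3 and Chd7 (57.5 each). They were followed by Taok2 and Lcp2 (55 each), Dusp10 and Atf4 (52.5 each), and Ttc3 and Srp19 (2 of 14 genes tied at 50). Lcp2, the adaptor SLP-76 of immune receptor signalling (chromosome 11, 34046920 to 34092295), was detected in 8 of 8 photoconverted cells and in 45% of depth-matched cells. Its mean was 654 CPM in photoconverted and 406 in all non-photoconverted cells. Atf4, a transcription factor of the amino acid stress response (chromosome 15, 80255184 to 80257541), was detected in 6 of 8 and in 22.5%. Dusp10 was the exception by mean CPM, at 221 in photoconverted against 311 in non-photoconverted cells. The largest differences the other way were at Smg1 (-57.5 percentage points), Il17rb and Nap1l1 (-45 each), Pbrm1, Tcp1, Lsp1 and Srsf2 (-42.5 each), Fam102a, Brd2, Lax1 and Tcf25 (-40 each) and Il7r (1 of 2 genes tied at -37.5), and all 12 were also lower by mean CPM. Il17rb (chromosome 14, 29996135 to 30008896) had a mean of 25 against 136 CPM, and Il7r (chromosome 15, 9505788 to 9530176) 179 against 445 CPM. Over the 1279 genes the median difference was 12.5 percentage points, and 0.19 as log2 ratio of mean CPM. These values hold for these genes only, since a gene could enter through its detection in photoconverted cells. These genes were picked for size among 8 cells, and their differences have no replicate check.

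Markers of other cell types were also looked for in the 106 cells of plate 1. At least 3 ILC2-like markers were detected in 93 cells, 8 of them photoconverted, and at least 3 T cell-like markers in 4 cells, 0 of them photoconverted. At least 3 ILC3-like markers were detected in 29 cells, 3 of them photoconverted, led by Ltb at 47.2% of cells. The most often detected markers of other types were Cst3 (myeloid, 33%), Kit (mast cell or basophil, also on some innate lymphoid cells, 21.7%), Pecam1 (stromal or endothelial, 8.49%), Cd79b (B cell, 4.72%), Nkg7 (NK cell or ILC1, 3.77%), Pcsk1 (endocrine, 1.89%) and Epcam (intestinal epithelium, 0.943%), and 0 cells held 3 markers of the myeloid, mast cell, stromal or NK cell lists, the ones of these with at least 3 measured markers. The measured markers of acinar and of erythroid cells were detected in 0 of 106 cells, which allows up to 2.83%. Clustering split the cells into an ILC2-like cluster of 96 cells with all 8 photoconverted cells and 89.8% of the non-photoconverted ones (82 to 95%), and an unnamed cluster of 10 non-photoconverted cells with a median of 739 genes.

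Across all 4 plates, where wells can be compared without gene names, photoconverted wells had more detected rows than non-photoconverted wells. The medians were 2265 against 1038 on plate 1, 707 against 356 on plate 2, 634.5 against 328.5 on plate 3 and 611.5 against 435 on plate 4, with empty wells at 119, 75.5, 108 and 67. The log2 ratio was 0.89 ± 0.28 (SD, n = 4 plates), a factor of 1.85, and the exact within-plate swap test gave a two-sided p of 0.125, the smallest that its 16 arrangements allow (adjusted p = 0.125 over 3 measures). The mean log2 ratio was 1.06 in the first sort batch (plates 1 and 2) and 0.72 in the second (plates 3 and 4). Reads per well (log2 ratio 0.66 ± 0.50, SD, n = 4) and the share of wells that passed the filter (0.72 ± 0.50) were also higher in 4 of 4 plates, each with exact p = 0.125. On plate 1 the passing shares were close, at 66.7% of photoconverted and 64.9% of non-photoconverted wells. Reads per well count all rows, spike-ins included, and do not measure cell RNA. On plate 3 their median was 77976 in non-photoconverted and 80805 in empty wells. Among wells with at least 1000 genes (rows of any kind on plates 2 to 4) the log2 ratio of detected rows was 0.15 and higher in 2 of 4 plates. Such a limit on the measured quantity shrinks the ratio whatever its cause. It also left few photoconverted wells on plates 2 and 4, where the upper quartile of detected rows was 919 in 9 wells and 976.75 in 12 wells.

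**Figure D4:**
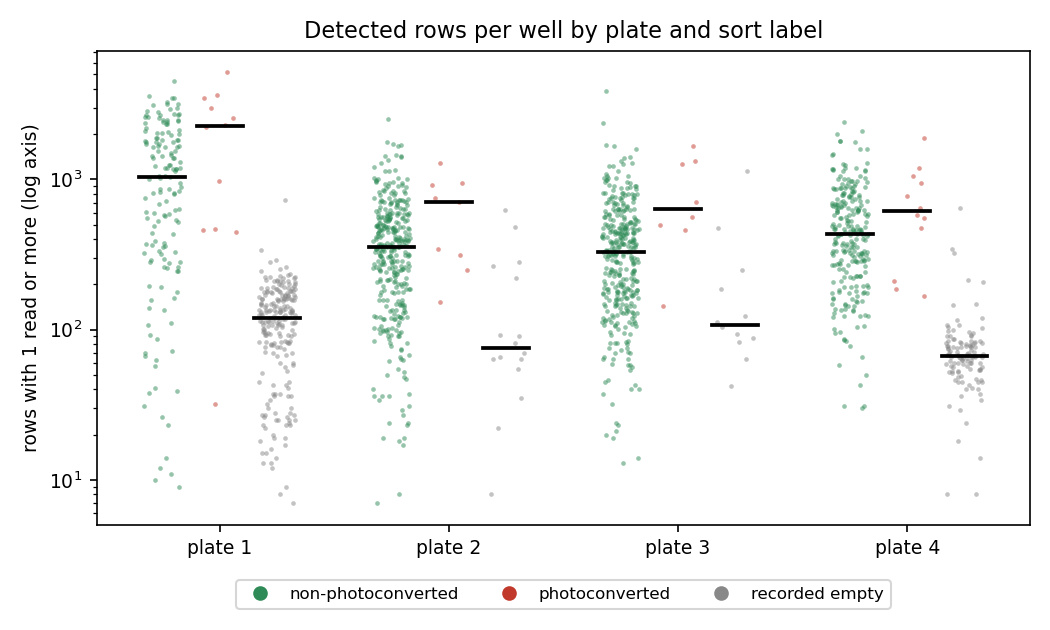
Table rows with 1 read or more in each well (log axis) by plate, for non-photoconverted (green), photoconverted (red) and empty wells (grey), with medians as black bars. The photoconverted median is above the non-photoconverted one on 4 of 4 plates.

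The colours parted at a boundary of the recorded red fluorescence. Non-photoconverted cells reached at most 1927 units and photoconverted cells started at 2002, as a sort boundary sets by construction, and 12 of the 41 photoconverted cells lay below 2500. The median fluorescence of photoconverted cells exceeded that of non-photoconverted cells by 4110 ± 1761 units (SD, n = 4 plates, exact p = 0.125). The boundary fixes this direction, so the planned test says nothing further.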

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

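The tests of well position, of brightness within non-photoconverted wells, of single cells and of RNA content were written down before their results were seen, and all other tests below, with the leave-outs of drawn-down values, after. Plate 1 lay apart from the other 3 plates in 3 of 12 quantities per plate and colour, where chance sets a plate apart in about 1 of 20: the median of detected rows in non-photoconverted wells (1038), the same in photoconverted wells (2265), and the median reads in photoconverted wells (361794). The 3 quantities come from the same wells and are not independent. Of 366 wells recorded as empty, 5 had more rows with 16 reads or more than the median non-photoconverted well of their plate, 2 on plate 2, 2 on plate 3 and 1 on plate 4, and no explanation for these was tested.

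Photoconverted wells had more detected rows on 4 of 4 plates. Position on the plate would have removed the difference against the nearest 10 non-photoconverted wells in row-by-row order, but there the mean log2 ratio was 0.98. Against these wells it fell from 1.13 to 0.75 on plate 1 and rose on plates 2, 3 and 4. Closeness between wells of different rows was not taken into account. Better amplification or deeper sequencing would have raised spike-in reads too, if equal amounts were added, but on plate 1 their ratio was 0.914; plates 2 to 4 were left open, since their spike-in rows were not identified. A larger share of failed non-photoconverted wells stayed open: among wells that passed the filter the log2 ratio was 0.50, but that filter is a limit on detected rows and would shrink the ratio whatever its cause, so this value decides nothing. On plate 1 the shares of wells that passed were close, at 66.7% of photoconverted and 64.9% of non-photoconverted wells, but this is 1 plate with 12 photoconverted wells. Brighter cells with more RNA, whatever their colour, would have given a positive rho of fluorescence with detected rows within non-photoconverted wells. The rhos were -0.106, 0.0486, 0.0529 and 0.0989 on plates 1 to 4. The highest lay just under the limit written beforehand for counting against this explanation. It was close to that limit and came from a narrow range of fluorescence, so the explanation was left open. A difference in RNA content between photoconverted and non-photoconverted ILC2 is the biological explanation and was not tested separately.

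Glycolysis genes lay above random lists in the photoconverted cells of plate 1. Greater depth of these cells would have brought the list towards random lists against depth-matched cells. Depth here means the genes and reads of genes found per cell. It does not mean deeper sequencing, since median spike-in reads were 59283.5 in photoconverted and 67405 in non-photoconverted cells. There its lowest percentile over share, drawn-down share and mean CPM was 99.16. The drawn-down share lay at 99.67, and at 99.04 or more without any 1 photoconverted cell. These values argue against depth as the whole explanation in these 8 cells, although the percentile is not a test. The drawn-down value of 99.67 also met the limit written beforehand for counting against RNA content. That limit was set aside, because cells were matched on genes detected and not on RNA content, so RNA content stayed open. A single cell could not be excluded, since without photoconverted cell 6 the list lay at 94.11. A metabolic difference between the colours remains a hypothesis from 8 cells of 1 plate.

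The effector cytokine list lay above random lists by depth-matched share. Against depth-matched cells it lay at 99.96 drawn down and at 98.66 by mean CPM, but leaving out 1 photoconverted cell took the drawn-down value as low as 75.24, so these values do not exclude depth beyond their spread. A single cell may carry its place outside the central 95%, since without photoconverted cell 1 it lay at 86.36. General activation would have raised immediate early genes, and their percentile of 54.33 did not decide it.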

How the results depend on the processing

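The cell filters, equal cell numbers, drawing down, clustering settings and leaving out plates were planned, and the other alternatives here were chosen after the data were seen. The mean log2 ratio of detected rows per well stayed above 0, from 0.15 (at least 1000 genes, higher in 2 of 4 plates, exact p = 0.75) to 1.02, and 0.72 without wells near the sort boundary (3 of 4 plates, exact p = 0.25); without 1 plate each it was 0.81 to 1.02. A p under 0.05 was not possible in any of these. The lists outside the central 95% numbered 5, and 3 with at least 1000 genes, 2 with the same number of cells from each colour, 3 at 1 read, 3 without cells near the sort boundary, 2 without the 2 dividing non-photoconverted cells, 7 drawn down, 7 drawn down and depth-matched, 7 by mean CPM, 7 by depth-matched mean CPM, 6 at 64 reads, and 3 to 7 without 1 photoconverted cell each.

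List percentiles moved as follows, and the cause was not tested. With the same number of cells from each colour (8 and 8), cell cycle lay at 33.775, glycolysis at 83.82, ILC2-like at 76.31 and neurotransmitter receptors, now below the middle, at 35.575. At 1 read, cytokines lay at 67.665, neurotransmitter receptors at 88.31 and ILC2-like, below the middle, at 28.735; at 64 reads neurotransmitter receptors lay at 51.38. By mean CPM cytokines lay at 92.69 and cell cycle at 2.915. Against all non-photoconverted cells, cytokines lay at 33.07, below the middle, and ILC2-like at 59.165. Without cells near the sort boundary, cytokines lay at 96.49, neurotransmitter receptors at 53.805 and ILC2-like at 61.34. ILC2-like also lay at 92.945 with at least 250 genes, 39.625 with at least 1000 (below the middle) and 97.395 without a mitochondrial limit, and neurotransmitter receptors at 97.445 with at least 1000. Without the 2 dividing non-photoconverted cells, cell cycle lay at 52.345 (these cells were chosen for holding its genes, so the move upward is in part fixed), neurotransmitter receptors at 90.325 and ILC2-like at 95.175. Without 1 photoconverted cell each, the ranges were 86.36 to 99.85 (cytokines), 54.925 to 99.74 (neurotransmitter receptors), 0 to 0.01 (cell cycle), 94.11 to 99.805 (glycolysis) and 40.275 to 99.22 (ILC2-like). Leaving out single dividing cells does not test the cell cycle list, since either of the 2 suffices: without 1 depth-matched cell each it lay at 0 to 0.04, glycolysis at 98.91 to 99.97, cytokines at 97.925 to 99.665, neurotransmitter receptors at 95.32 to 99.48 and ILC2-like at 91.765 to 98.535. Of the other lists, 25 values lay outside, among them interferon response at 99.08 drawn down, 99.88 drawn down and depth-matched, 99.96 by depth-matched mean CPM and 99.625 at 64 reads, and tissue egress at 98.76 drawn down. Among named genes, 3 of 240 values reversed: Pbrm1 (12.5 percentage points) and Tcf25 (25) with the same number of cells, and Fam102a (12.5) at 64 reads.

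DESeq2, size factors, count filters, camera, fry and all feeding state tests were not run, since no gene test could be fitted, nor was leaving out plates for genes and clusters, which rest on 1 plate. Plate centring had nothing to centre. At resolution 0.8, with 5 clusters, no cluster equalled the ILC2-like one; at resolution 0.3 and with at least 1000 genes all cells formed 1 cluster. Depth limits genes seen in few cells: 0 of 8 cells allows up to 37.5%.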

Other observations

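At the finer clustering resolution of 0.8, a cluster of 30 cells with a median of 2376 genes held 6 of the 8 photoconverted cells of plate 1, and a cluster of 35 cells the other 2. This setting was planned as an alternative, and its clusters were not named. Ribosomal protein genes, a list added after the data were seen, lay at the 18.1th percentile by depth-matched share and at the 0.07th by drawn-down share. By mean CPM, the fatty acid uptake and oxidation list lay at the 99.5th percentile, intestinal ILC2 at the 99.1th, glucocorticoid response at the 98.3th and NK or ILC1-like markers at 1.645. Their depth-matched shares lay inside the central 95%, but intestinal ILC2 lay outside by other depth-matched measures, at 98.89 drawn down and 99.37 by mean CPM, and at 98.365 by share at 64 reads.

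The names of the rows of plates 2 to 4 were weighed by 2 tests chosen after the mismatch was seen. True differences in expression between plates would leave the spike-ins in place, assuming that the same mix was added to each well, which the labels do not state, but the highest rho of their rows with plate 1 was 0.102. A table made by placing each plate's own list of detected genes side by side would hold rows with reads on every plate, and 0 rows with values lacked reads. A candidate explanation is therefore that the names belong to plate 1 alone, and the names of the other plates were not recovered here.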
